A study of Homo sapiens with 12 samples.

How the data were processed

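RNA of LNCaP cells was hybridised to 12 Agilent 1-colour (Cy3) arrays, 3 per group for DMSO, TSA, NCC-149 and OBP-801. Groups, doses and the time of 24 h were taken from the labels. Per the file headers, images were read with Agilent Feature Extraction 10.10.1.1, and the array design gives positions in genome build hg19. Per the file headers, the processed signal of each spot is an intensity on a linear scale after background subtraction and detrending, not normalized between arrays. The deposited value table holds the same intensity, equal to the processed signal within 0.5% in every column and exactly in 1. It is linear, uncentred and without normalization between arrays, and no direction is involved. Its column medians were 98.3, 96.5 and 90.4 for TSA, 76.1, 73.6 and 73.5 for DMSO, 68.6, 69.9 and 60.65 for NCC-149 and 105, 105 and 112 for OBP-801 (replicates 1, 2 and 3 each).

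Signals were taken as log2 of the processed signal minus each array's 75th percentile over non-control probes. Control spots were left out, as were 24 spots marked as uneven, and 0 spots were saturated. The spots of a probe were averaged, 58717 spots giving 42405 probes. Probes were named through the RefSeq accession in the files, matched without version to a table of assembly GRCh38.p14. That table was used for symbols and for which genes are neighbours, and no coordinates from it are given here. By this naming 25422 probes had 1 symbol, 0 had several and 16983 had none. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which left 28519 probes, 19716 of them with a symbol. A gene took the probe with the highest mean signal, 15287 genes in all. Of these, 3705 had several probes, and probes called in opposite directions occurred in 188 genes for TSA, 4 for NCC-149 and 199 for OBP-801, each against DMSO.

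All 12 arrays entered a linear model with 1 mean per group in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, two-sided moderated test, 8 residual degrees of freedom) with the R package data.table (version 1.17.8). The 6 pairwise comparisons were each adjusted by Benjamini and Hochberg over all genes, and a gene was called at an adjusted p under 0.05, then counted again at 2-fold. The median residual SD was 0.076 on the log2 scale. There were 28 gene lists with 469 distinct genes, 450 of them on the array. Lists were tested with camera (preset correlation 0.01), which compares a list with all other genes, and adjusted over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives, and fry tests whether a list's own genes moved 1 way on balance, not whether they differ from other genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

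The groups, tests, gene lists and alternatives were fixed before the data were examined, as was the rule for genes named in the text. For each compound against DMSO the rule took the 6 largest rises and 6 largest falls among called genes well above background on all 6 arrays and changed the same way in every pairing of arrays. It added 4 genes each way with the largest bounds among those below background in 1 group, up to 4 members of each list with the smallest p, and a fixed set with KLK3, KLK2, TMPRSS2, FKBP5, CDKN1A, MKI67 and 5 HDAC genes. Between compounds it took 5 genes each way.

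The fit was tested on simulated data for all 15287 genes, 50 changed at each of 4 fold sizes. At 1.2-fold it recovered 38% of changed genes for TSA against DMSO, 48% for NCC-149, 30% for OBP-801 and 44% for TSA against OBP-801. At 1.5-fold the shares were 86%, 82%, 96% and 78%, and at 2-fold 94%, 88%, 92% and 98%. False calls numbered 10, 17, 9 and 11. Far more genes were called against DMSO in the measured data, 13240 for TSA, 3301 for NCC-149 and 13203 for OBP-801. The cut-off after adjustment depends on how many genes change. These shares and false calls therefore hold for few changed genes and do not describe those comparisons with DMSO.

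The alternatives were quantile normalization, median centring, scaling on 7 spike-in probes, normexp background correction with an offset of 50, the deposited table, no filter on dim probes, probes above background on all 12 arrays, the mean over a gene's probes, eBayes with trend and robust, the replicate number or the slide as a block, fits of only the 2 groups, and leaving out each array in turn. The files hold no mean signal, so normexp used the median signal with the median local background. Probes without a symbol stayed out of the tests of genes, and those for long intergenic noncoding RNAs are given in the closing section. Dates were not used, and the slide and the row on the slide were read from the barcode in the file headers. Some genes and 1 of the gene lists are not reported here.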

Results

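The series measured RNA levels in LNCaP cells, a human prostate cancer line from a lymph node metastasis. Cells were treated for 24 h with 1 of 3 inhibitors of histone deacetylases (HDACs) or with the solvent DMSO. The inhibitors were trichostatin A (TSA, 1 µM), NCC-149 (2 µM) and OBP-801 (200 nM), so the doses differed. Each of the 4 groups had 3 arrays, 12 in all. The 75th percentile of signal was 1537 to 1629 on DMSO arrays, 1184 to 1288 on TSA arrays, 1276 to 1464 on NCC-149 arrays and 1412 to 1491 on OBP-801 arrays. The share of probes well above background was 61.3% ± 0.28 (SD, n = 3) for DMSO and 61.3% ± 1.16 for NCC-149. It was 66.7% ± 1.31 for TSA and 67.6% ± 1.0 for OBP-801. TSA and DMSO arrays shared slide 1, and NCC-149 and OBP-801 arrays shared slide 2. The comparisons of TSA with DMSO and of NCC-149 with OBP-801 therefore lay within a slide. The other 4 of the 6 comparisons cross slides, and no fit with slide as a term gives a value for them. Log2 changes below carry the standard error of the fit, and a gene was called at an adjusted p under 0.05. The number of arrays limits the precision of every value. The titles number the arrays of a group and do not say whether they are separate cultures or repeats of 1 culture. Every p therefore measures spread between arrays of a single cell line.

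TSA against DMSO asked what this HDAC inhibitor changed in LNCaP cells. MYC, a driver of growth and ribosome production, fell by 6.29 ± 0.044 on the log2 scale (n = 3 against 3, adjusted p = 2.6e-14). SPDEF, a transcription factor of luminal prostate epithelium, fell by 5.98 ± 0.057. C9orf152 fell by 6.39, EFS fell by 5.43, RIMS1 fell by 5.22 and ADAM7 fell by 5.10. The largest rises among genes well above background in both groups were those of GOLGA6L6 (7.66 ± 0.112), BASP1 (7.55), CEND1 (7.26), RPL3L (7.01), DIO3 (6.91) and IGF2 (6.83). GOLGA6L6 belongs to a family of near-identical copies, so its probe is uncertain. BASP1 and CEND1 are known from neurons, and IGF2, which rose by 3.24 on another probe, codes for a growth factor. Of 15287 genes tested, 13240 were called, 7910 up and 5330 down. Of these, 5767 changed at least 2-fold, 3840 up and 1927 down, and with median centring 2510 up and 4216 down.

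Many of the rises under TSA started from signal that could not be told from background. In 1075 called genes, no DMSO array and every TSA array was well above background, and in 93 the reverse held. Of the rises of at least 2-fold, 27.8% were in genes of the former kind. A fold for such a gene is a lower bound, the mean of the bright group against the dim group's mean of the lowest signal well above background on each array or the probe's own signal, whichever was higher. MIR7-3HG, the host gene of a microRNA, rose at least 1900-fold, CYP4F3 at least 260-fold, AREG, an EGF receptor ligand, at least 207-fold and FAM43B at least 159-fold. SLC22A3 fell at least 18.3-fold, GIMAP2 at least 14.3-fold, BRDT at least 12.3-fold and DSC1 at least 9.56-fold.

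Androgen-dependent genes fell together under TSA. KLK3, which codes for prostate-specific antigen, fell by 4.03 ± 0.060 (adjusted p = 1.2e-12), its neighbour KLK2 fell by 4.30 and the androgen-induced protease gene TMPRSS2 fell by 4.68. SLC45A3 fell by 4.80 and FKBP5, another androgen-induced gene, fell by 2.26 ± 0.067. Of 29 measured androgen-induced genes, 26 fell and 2 rose (28 called when adjusted over the list alone). Their median log2 change was -1.91 (camera adjusted p = 2.0e-09), and the call held with an estimated correlation (adjusted p = 0.00218). Among transcription factor genes of prostate epithelium, FOXA1 fell by 3.48, GRHL2 fell by 2.58 and HOXB13 fell by 2.20. Of 6 measured androgen-repressed genes, 3 rose and 3 fell (6 called when adjusted over the list alone, median -0.48, adjusted p = 0.501). MET, a receptor kinase, rose by 3.37 while ACKR3 fell by 4.48 and UGT2B15 fell by 2.84.

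Genes of proliferation and ribosome production fell under TSA. Of 36 DNA replication genes, 31 fell and 2 rose (33 called when adjusted over the list alone), with a median of -1.01 (adjusted p = 2.0e-09, and adjusted p = 0.0564 with an estimated correlation). TYMS, the thymidylate synthase gene, fell by 3.34, the licensing factor CDT1 fell by 2.20 and CDC25A fell by 2.07. Of 25 mitotic genes, 22 fell and 2 rose (24 called when adjusted over the list alone, median -0.82, adjusted p = 1.5e-06, and adjusted p = 0.0654 with an estimated correlation). AURKB fell by 1.81 and CDK1 fell by 1.73, and the proliferation marker MKI67 fell by 0.92 ± 0.075 (adjusted p = 5.6e-07). Other MKI67 probes gave -1.82 and -0.21. Of 22 homologous recombination genes, 16 fell and 3 rose (19 called when adjusted over the list alone, median -0.56, adjusted p = 3.3e-04, and adjusted p = 0.0654 with an estimated correlation). BARD1 fell by 1.89. Of 21 ribosome biogenesis genes, 20 fell (20 called when adjusted over the list alone), with a median of -0.96 (adjusted p = 2.3e-07). That call also held with an estimated correlation (adjusted p = 0.0123). NOP56 fell by 1.62, DKC1 fell by 1.60 and NCL, nucleolin, fell by 1.39. The CDK inhibitor gene CDKN1A rose by 1.21 ± 0.076 (adjusted p = 6.3e-08) and CDKN1C by 5.36. CDKN2B rose at least 5.62-fold, and CDKN2C fell by 0.83. Of the 7 CDK inhibitor genes 4 rose and 3 fell (7 called when adjusted over the list alone, median 1.21, adjusted p = 0.823).

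Neuronal, metal-binding and histone genes rose under TSA. Of 17 measured neuroendocrine and neuronal markers, 14 rose and 2 fell (16 called when adjusted over the list alone), with a median of 3.61, or 2.17 with bounds for the 6 members below background in 1 group (adjusted p = 0.00645, and adjusted p = 0.0654 with an estimated correlation). The adhesion gene NCAM1 rose at least 110-fold and STMN2 at least 63.4-fold, while the neuronal tubulin TUBB3 rose by 3.65 ± 0.062. The call of this list ended when only probes above background on all 12 arrays were tested (median 0.32). All 10 metallothionein genes, which bind metal ions, rose (10 called when adjusted over the list alone, median 3.31, adjusted p = 2.1e-04, and adjusted p = 0.15 with an estimated correlation), MT1E by 3.65 and MT1X by 3.49. Of 17 genes known to rise under HDAC inhibitors, 17 rose (17 called when adjusted over the list alone), with a median of 2.70, or 1.83 with bounds (adjusted p = 2.3e-05, and adjusted p = 0.0654 with an estimated correlation). DHRS2 rose by 5.72 and GSN, gelsolin, by 2.96. CDKN1C and MT1X are members of this list as well. Of 15 histone genes, 11 rose and 2 fell (13 called when adjusted over the list alone, median 1.13, adjusted p = 0.0365, and adjusted p = 0.426 with an estimated correlation), and H2BC21 rose by 2.06. This call ended when only TSA and DMSO arrays were fitted.

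Luminal epithelial markers fell under TSA, with 12 of 14 lower and 2 higher (14 called when adjusted over the list alone, median -0.75, adjusted p = 0.00221, and adjusted p = 0.0654 with an estimated correlation). KRT19, a keratin, fell by 2.46 and the splicing factor ESRP2 fell by 2.10, while CD24 rose by 4.64. Of 11 acetyltransferase genes, 9 fell and 2 rose (11 called when adjusted over the list alone, median -0.69, adjusted p = 0.0154, and adjusted p = 0.0654 with an estimated correlation). KAT2A fell by 1.86, and NCOA3 rose by 0.97. Both calls ended with median centring of the arrays, which lowered all genes and gave medians of -1.37 and -1.31. The lists that follow did not pass the list test under TSA. Their medians were 1.45 (1.36 with bounds) for 12 mesenchymal and fibroblast markers, 0.87 for 17 antigen presentation genes, 0.45 for 9 leukocyte and endothelial markers and 0.45 for 13 cancer-testis antigen genes. They were 0.35 for 23 cholesterol synthesis genes, 0.27 for 17 deacetylase genes, 0.13 for 7 basal epithelial markers, -0.20 for 18 unfolded protein response genes and -0.27 for 11 Polycomb and DNA methyltransferase genes. They were -0.45 for 20 p53 target genes, -0.54 for 16 BCL2 family genes, -0.67 for 11 fatty acid synthesis genes and -0.88 for 10 death receptor genes. For 14 heat shock genes the median was 0.28 and the mean 0.50, while the test's direction was down (adjusted p = 0.838). With median centring the medians of the leukocyte, cancer-testis, cholesterol, deacetylase, basal and heat shock lists turned negative. Death receptor genes passed without the filter on dim probes (median -0.50), with normexp (-0.72), with spike-in scaling (-1.11) and without TSA replicate 1 (-0.89). Mesenchymal markers passed with median centring (0.83) and antigen presentation genes with quantile normalization (0.95). Within these lists VIM, vimentin, rose by 4.65, INSIG1, a sterol sensor, by 3.93, ATF3 by 2.78 and the chaperone gene HSPA1A at least 6.68-fold. XBP1 fell by 2.62, CFLAR fell by 3.17, BID fell by 1.86 and UHRF1 fell by 2.16.

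HDAC genes themselves changed unequally under TSA. HDAC3 rose by 1.42 ± 0.051 (adjusted p = 6.4e-10), and HDAC2 fell by 0.54 ± 0.059 (adjusted p = 6.8e-06). HDAC7 fell by 2.58 and HDAC5 rose by 1.59. The log2 changes of HDAC1 (0.08, a call that ended without each array but DMSO replicate 1), HDAC6 (0.27) and HDAC8 (0.08) turned negative with median centring of the arrays (-0.54, -0.35 and -0.54). For HDAC6 another probe fell by 0.385 (adjusted p = 0.00378), and for HDAC8 another probe fell by 0.387 (adjusted p = 4.1e-04). The median log2 change of all genes was 0.225 under TSA, and other ways of scaling the arrays moved it by -0.166 (quantile), -0.222 (spike-in) and -0.623 (median centring). All 3 shifts are downward, so rises smaller than them have no settled direction.

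**Figure D1:**
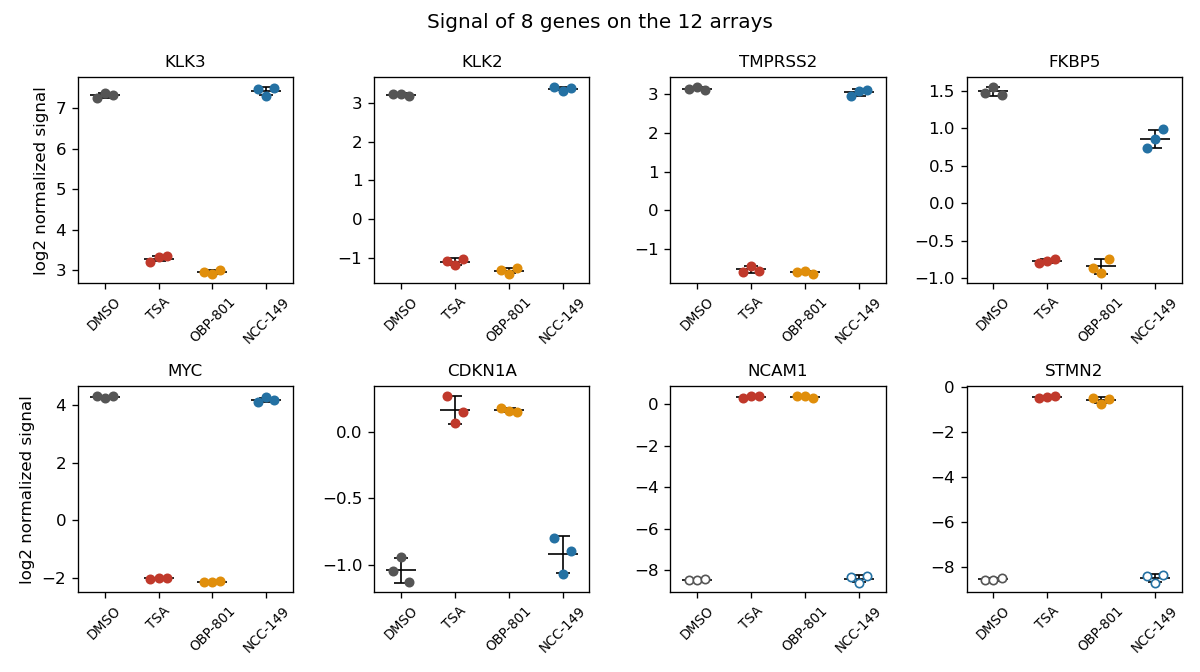
Log2 normalized signal of 8 genes on each of the 12 arrays, with the group mean and SD as lines and open circles where a probe was not well above background. KLK3, KLK2, TMPRSS2 and MYC lay lower on all 3 TSA and all 3 OBP-801 arrays than on any DMSO or NCC-149 array, and NCAM1 and STMN2 were well above background on TSA and OBP-801 arrays alone.

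OBP-801 against DMSO asked the same for the second inhibitor, across slides. MYC fell by 6.41 ± 0.044 (n = 3 against 3, adjusted p = 3.0e-14), C9orf152 fell by 6.58, SPDEF fell by 6.25, EFS fell by 5.64, RIMS1 fell by 5.44 and ADAM7 fell by 5.35. BASP1 rose by 7.54 ± 0.099, GOLGA6L6 by 7.44, CEND1 by 7.25, RPL3L by 6.96, IGF2 by 6.75 (3.41 on another probe) and ANKRD35 by 6.71. KLK3 fell by 4.36 ± 0.060, KLK2 fell by 4.53, TMPRSS2 fell by 4.75 and FKBP5 fell by 2.33. CDKN1A rose by 1.2, HDAC3 by 1.45 and TUBB3 by 3.43, while HDAC2 fell by 0.56 and MKI67 fell by 1.11 (-1.89 and -0.29 on other probes). The log2 changes of HDAC1 (0.03), HDAC6 (0.18) and HDAC8 (0.04) turned negative with median centring, and another HDAC8 probe fell by 0.305 (adjusted p = 0.0021). Of 15287 genes, 13203 were called, 7829 up and 5374 down, and 5764 changed at least 2-fold, 3814 up and 1950 down. With median centring 2541 rose and 4051 fell at least 2-fold.

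MIR7-3HG rose at least 2095-fold under OBP-801, CYP4F3 at least 223-fold, AREG at least 200.3-fold and SYT11 at least 160-fold. TBX15 fell at least 20.9-fold, GIMAP2 at least 16.8-fold, BRDT at least 14.4-fold and INPP4B, a phosphatase of phosphoinositide signalling, at least 10.4-fold. In 1131 called genes, no DMSO array and every OBP-801 array was well above background, and in 85 the reverse held. Of the rises of at least 2-fold, 29.2% were in genes of the former kind.

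Among the lists, 26 of 29 androgen-induced genes fell under OBP-801 and 1 rose (27 called when adjusted over the list alone, median -2.04, adjusted p = 1.0e-09, and adjusted p = 0.00196 with an estimated correlation). Of 21 ribosome biogenesis genes 18 fell (18 called when adjusted over the list alone, median -0.94, adjusted p = 2.8e-06, and adjusted p = 0.0221 with an estimated correlation). These were the 2 lists whose call held with an estimated correlation. DNA replication (median -1.01), mitotic (-0.87) and homologous recombination genes (-0.53) fell with the preset correlation, as did luminal markers (-0.82), acetyltransferases (-0.62) and death receptor genes (-0.93). Neuronal markers (median 3.43, or 2.14 with bounds), metallothioneins (3.23, or 3.10 with bounds), genes known to rise under HDAC inhibitors (2.77, or 1.65 with bounds) and histone genes (1.09) rose with it. With an estimated correlation these 10 lists had adjusted p of 0.0636 to 0.367. NCAM1 rose at least 109-fold, DHRS2 rose by 5.65, MT1H by 3.54 and H2BC21 by 2.13. The death receptor gene CFLAR, an inhibitor of caspase 8, fell by 3.07 and TNFRSF10A fell by 2.06. That list's call ended with quantile normalization, with median centring and with probes above background on all 12 arrays, and that of acetyltransferases ended with the latter 2. The call of neuronal markers also ended with probes above background on all 12 arrays, where their median was 0.34. The other 15 lists did not pass, with medians from -0.67 for fatty acid synthesis genes to 1.42 (1.1 with bounds) for mesenchymal markers. For heat shock genes the median was 0.20 and the mean 0.48, and the test's direction was down. Antigen presentation genes passed with quantile normalization (median 0.87) and fatty acid synthesis genes without the filter on dim probes (-0.63).

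TSA against OBP-801 asked whether the compounds differed at the doses used, which were not matched. The comparison crosses slides and rows on the slide. Its differences in genes and in lists therefore cannot be told apart from effects of slide and row. The telomere protein gene POT1 was higher under TSA by 0.97 ± 0.102 on the log2 scale (n = 3 against 3, adjusted p = 0.00783), COL14A1, a collagen gene, by 0.95 ± 0.131, FGG by 0.71, MCRIP1 by 0.71 ± 0.048 (adjusted p = 7.3e-04) and DIO3 by 0.57. TWNK, the mitochondrial helicase gene, stood at -0.53 ± 0.065 (adjusted p = 0.0117), CARD9 at -0.50, L3HYPDH at -0.48, SNHG1 at -0.47 and TRIM48 at -0.47. All 10 of these calls ended with spike-in scaling, which moved the median of all genes by -0.104, though the log2 differences remained (POT1 0.86, COL14A1 0.85, MCRIP1 0.60 and TWNK -0.63). POT1, MCRIP1 and SNHG1 kept theirs without any 1 array, and TWNK lost it without TSA replicate 3. COL14A1 lost its call without TSA replicate 1 or 3 or OBP-801 replicate 1 or 3. FGG lost it without each array but OBP-801 replicate 3, and DIO3, CARD9, L3HYPDH and TRIM48 without each of the 6. KLK3 stood 0.33 higher under TSA (adjusted p = 0.0326), a call that ended without each of the 6 arrays, while KLK2 (0.23, adjusted p = 0.0563) did not pass. Of 15287 genes, 224 were called, 122 higher and 102 lower. A single gene, FAT4, named after its value was seen, passed 2-fold, and no OBP-801 array had it well above background. For 14896 genes, or 97.4%, the 95% confidence interval of the difference lay within 2-fold in either direction.

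Ribosome biogenesis genes were lower under TSA than under OBP-801, 7 of 21 called lower (12 called when adjusted over the list alone, median -0.12, adjusted p = 2.2e-06, and adjusted p = 0.0312 with an estimated correlation). Metallothioneins (median 0.15, 9 of 10 called when adjusted over the list alone but not over all genes), mitotic genes (0.07), fatty acid synthesis genes (0.05) and luminal markers (0.07) were higher with the preset correlation. Their adjusted p with an estimated correlation was 0.274, 0.276, 0.188 and 0.274. The medians of the other 23 lists ran from -0.05 to 0.14, and none of these passed. No gene was called with spike-in scaling by limma, where 2040 had an unadjusted p under 0.05, and 18 were called when only these 2 groups were fitted. Without any 1 of the 6 arrays 18 to 36 genes were called, fewest without TSA replicate 3. With spike-in scaling the medians of mitotic genes (-0.032), fatty acid synthesis genes (-0.052) and luminal markers (-0.036) turned negative and their calls ended. The call of mitotic genes also ended with normexp, that of metallothioneins with quantile normalization (median 0.046), and that of fatty acid synthesis genes with median centring, normexp and only the 2 groups. The call of luminal markers ended under every alternative but the deposited table, probes above background on all 12 arrays, eBayes with trend and robust, fry and leaving out TSA replicate 3 or OBP-801 replicate 1. For deacetylase genes the median was 0.02 and the test's direction down, for homologous recombination genes the mean was 0.003 and the direction down, and for BCL2 family genes the median was 0 and the direction up.

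**Figure D2:**
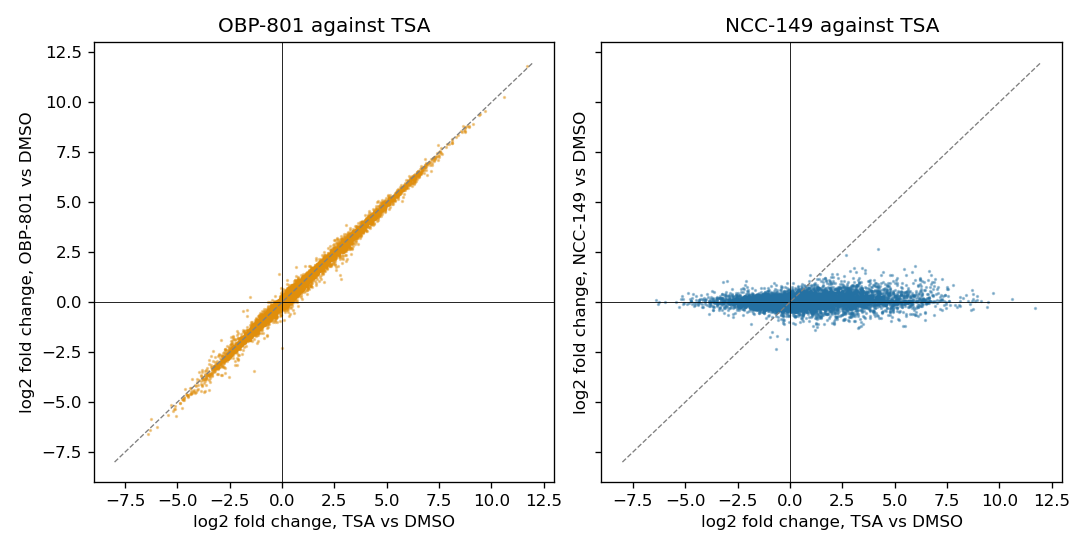
Log2 change of each tested gene under OBP-801 (left) and NCC-149 (right) against its log2 change under TSA, each against DMSO, with the line of equal change dashed. Points follow the line for OBP-801 (slope 0.991), whereas the NCC-149 changes stay near 0 across the range of TSA changes (slope 0.026).

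NCC-149 against DMSO asked the same for the third inhibitor, across slides, and its changes were small. LGALS7, a galectin of stratified epithelia, fell by 2.34 ± 0.16 (n = 3 against 3, adjusted p = 3.4e-05), TMEM221 fell by 1.71 and NPPC, which codes for a natriuretic peptide, fell by 1.18 ± 0.058 (adjusted p = 1.1e-05). CERCAM fell by 1.09, with another probe at 0.553 in the opposite direction, FAM177B fell by 1.06 and CCDC141 fell by 0.78. VSTM2L rose by 1.2 ± 0.24, DIO3, a deiodinase of thyroid hormone, by 1.16 ± 0.10 (adjusted p = 1.3e-04), IFI27L2 by 1.15, OR51E1 by 1.09, ADAM18 by 1.07 and EMID1 by 1.06. From signal below background on DMSO arrays, SLC51A rose at least 2.24-fold, PCDHGC4 at least 2.10-fold, FGF9 at least 1.83-fold and RSPO4 at least 1.64-fold. Another FGF9 probe was not called (0.221, adjusted p = 0.528). CMA1 fell to below background at least 1.73-fold, ZDHHC22 at least 1.66-fold, TCEANC at least 1.55-fold and OR1D2 at least 1.55-fold. The call of ADAM18 ended without each of the 6 arrays, that of EMID1 without each DMSO array and that of FGF9 without DMSO replicate 2 or 3. That of CMA1 ended without each DMSO array and NCC-149 replicate 1 or 3, and those of TCEANC and OR1D2 without DMSO replicate 1 or NCC-149 replicate 1 or 2. TCEANC also lost it without DMSO replicate 3 and OR1D2 without DMSO replicate 2. The calls of TMEM221 and PCDHGC4 ended when only the 2 groups were fitted, that of CERCAM with the mean over probes and that of ZDHHC22 with normexp. The step from TSA to OBP-801 crosses the same slides, and in a test chosen after the values were seen it was subtracted from that from DMSO to NCC-149. The subtraction takes out an effect of the slide alone. It enlarges any effect of row on the slide, which the steps cross in opposite directions. It also brings in any difference between TSA and OBP-801. The remaining log2 difference was 0.00 for CCDC141 (adjusted p = 0.991), and it did not pass for TMEM221 (-1.46), EMID1 (1.41), FGF9 (1.2), CMA1 (-2.26), TCEANC (-0.50) and OR1D2 (-0.81, adjusted p = 0.056 to 0.226 over the 6), where a difference remained in the same direction. It passed in the same direction for the other genes named here. Of 15287 genes, 3301 were called, 2130 up and 1171 down, with a median size of 0.253 on the log2 scale, and 69 passed 2-fold, 51 up and 18 down. On the probe used, 40 of the 51 rises had no DMSO array well above background. Genes with no DMSO array and every NCC-149 array well above background made up 7.8% of the 51. At 2-fold spike-in scaling gave 28 up and 29 down, probes above background on all 12 arrays 5 up and 5 down, and normexp a single gene, down. For 95.3% of genes the 95% confidence interval lay within 2-fold in either direction. When only NCC-149 and DMSO arrays were fitted 1452 genes were called, with spike-in scaling 840 (266 up and 574 down), and without DMSO replicate 3 2025.

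Under NCC-149 the androgen-induced FKBP5 fell by 0.63 ± 0.067 (adjusted p = 3.1e-04) and MKI67 fell by 0.41 ± 0.075 (adjusted p = 0.00454). After subtracting the step from TSA to OBP-801, FKBP5 passed (-0.56, adjusted p = 0.0047) and MKI67 did not (-0.22, adjusted p = 0.17). KLK3 (0.44, adjusted p = 0.00843) and KLK2 (0.39, adjusted p = 0.00777) passed there, though neither was called against DMSO. Each stood higher under TSA than under OBP-801, and the subtraction adds that difference. These passes therefore say little about NCC-149 against DMSO. The log2 change was 0.11 for KLK3 (adjusted p = 0.204), 0.16 for KLK2 (adjusted p = 0.0568), -0.10 for TMPRSS2 (adjusted p = 0.218) and 0.12 for CDKN1A (adjusted p = 0.287). It was 0.10 for HDAC1, -0.05 for HDAC2, -0.11 for HDAC3 and 0.08 for HDAC8, none of them called on the probe used. Another HDAC8 probe rose by 0.349 (adjusted p = 0.00903), and HDAC6 rose by 0.19 (adjusted p = 0.03), a call that ended with median centring, with spike-in scaling and without each of the 6 arrays. DHRS2, of the genes known to rise under HDAC inhibitors, fell by 0.58 ± 0.052 (adjusted p = 1.3e-04).

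DNA replication genes fell by small amounts under NCC-149, 26 of 36 called lower (30 called when adjusted over the list alone), with a median of -0.17 (camera adjusted p = 2.4e-16, and adjusted p = 0.0103 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell by 0.45 and MCM10 fell by 0.38. Of 25 mitotic genes 17 fell (19 called when adjusted over the list alone, median -0.23, adjusted p = 1.5e-14, and adjusted p = 0.013 with an estimated correlation), among them CDK1 by 0.37 and AURKA by 0.30. Of 22 homologous recombination genes 13 fell (17 called when adjusted over the list alone, median -0.19, adjusted p = 7.5e-11, and adjusted p = 0.0103 with an estimated correlation), among them the helicase gene BLM by 0.31. Of 11 fatty acid synthesis genes 8 rose (9 called when adjusted over the list alone, median 0.25, adjusted p = 1.4e-05, and adjusted p = 0.0103 with an estimated correlation), among them the desaturase genes FADS2 by 0.51 and SCD by 0.25. Of 17 antigen presentation genes 10 rose (10 called when adjusted over the list alone, median 0.22, adjusted p = 0.00177, and adjusted p = 0.0262 with an estimated correlation), among them the immunoproteasome gene PSMB8 by 0.58 and HLA-F by 0.41. This comparison crosses slides, and the subtraction used for single genes was not run on lists, so a share from the slide stays open. In the step from TSA to OBP-801, across the same slides, mitotic genes also moved down (median 0.07 for TSA against OBP-801). The medians of the other lists here moved against their NCC-149 direction (-0.03, -0.01, 0.05 and 0.04 for TSA against OBP-801, in the order given).

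A further 4 lists passed under NCC-149 with the preset correlation alone. Androgen-induced genes had a median of -0.04 with 7 of 29 lower and 2 higher (adjusted p = 0.0301, and adjusted p = 0.0859 with an estimated correlation), and acetyltransferase genes -0.07 with 3 of 11 lower (adjusted p = 0.0859 with it). The median was 0.09 for luminal markers with 5 of 14 higher (adjusted p = 0.124 with it) and 0.12 for p53 targets with 7 of 20 higher (adjusted p = 0.0989 with it). CD24 rose by 0.49 and GDF15, a stress cytokine, by 0.41. The median of luminal markers was -0.011 with spike-in scaling, which moved the median of all genes by -0.102. The calls of androgen-induced, acetyltransferase and p53 target genes ended without NCC-149 replicate 2 (medians -0.027, -0.035 and 0.122), and that of luminal markers without NCC-149 replicate 3 (0.078). The calls of androgen-induced genes, luminal markers and p53 targets also ended when only the 2 groups were fitted. Those of luminal markers and p53 targets ended with spike-in scaling (0.013 for p53 targets) and with normexp, and that of p53 targets with median centring. Small medians above 0 have no settled direction under that scaling. Among the 19 lists that did not pass, genes known to rise under HDAC inhibitors had a median of 0.06, neuronal markers 0.05, histone genes -0.02 and metallothioneins 0.01. Those of the other lists reported here ran from -0.03 for unfolded protein response genes to 0.12 for BCL2 family genes. The test's direction was down against a median of 0.06 for CDK inhibitor genes, 0.04 for mesenchymal markers, 0.03 for Polycomb and DNA methyltransferase genes and 0.01 for metallothioneins, whose mean was -0.003. For heat shock genes it was down against a mean of 0.065. Histone and ribosome biogenesis genes passed, with medians below 0, under quantile normalization (-0.041 and -0.046), median centring (-0.067 and -0.071), spike-in scaling (-0.124 and -0.128), normexp (-0.039 and -0.025) and the mean over probes (-0.023 and -0.032). Ribosome biogenesis genes also passed without the filter on dim probes (-0.027), and histone genes without DMSO replicate 2 (-0.045) or NCC-149 replicate 3 (-0.058). Neuronal markers (0.154) and unfolded protein response genes (-0.034) passed with normexp.

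**Figure D3:**
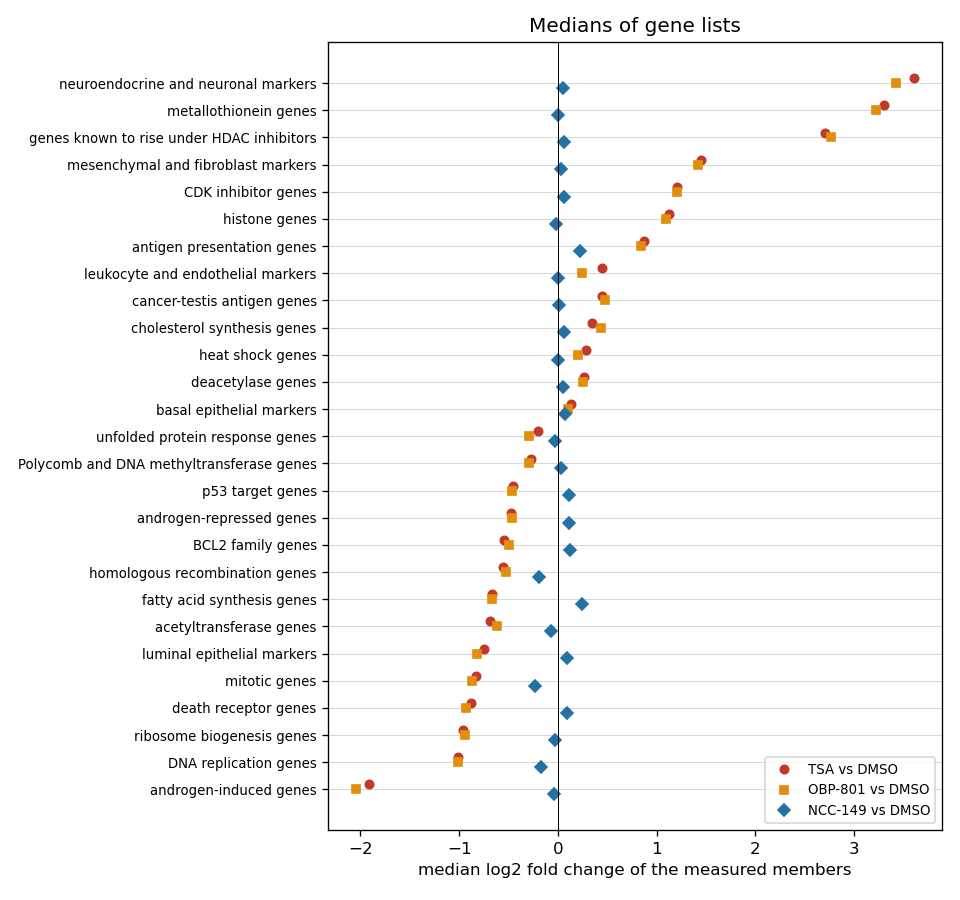
Median log2 change of the measured members of gene lists under each compound against DMSO. TSA and OBP-801 medians lie side by side from androgen-induced genes (-1.91 and -2.04) to neuronal markers (3.61 and 3.43), and NCC-149 medians lie between -0.23 and 0.25.

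NCC-149 against TSA and against OBP-801 asked how far the third inhibitor departed from the others at these doses. MYC was higher under NCC-149 by 6.19 ± 0.044 than under TSA (n = 3 against 3, adjusted p = 3.1e-14) and by 6.30 than under OBP-801 (adjusted p = 3.2e-14). C9orf152 was higher by 6.48 and 6.67, SPDEF by 5.98 and 6.25, EFS by 5.42 and 5.63 and RIMS1 by 5.40 and 5.62. GOLGA6L6 stood at -7.81 and -7.58, BASP1 at -7.25 and -7.24, CEND1 at -7.16 and -7.15, RPL3L at -6.89 and -6.84 and ANKRD35 at -6.77 and -6.71. KLK3 was higher by 4.15 and 4.47, KLK2 by 4.46 and 4.69, TMPRSS2 by 4.58 and 4.65 and FKBP5 by 1.62 and 1.70. CDKN1A stood at -1.09 and -1.08 and HDAC3 at -1.53 and -1.56, whereas HDAC2 was 0.49 and 0.50 higher. Against TSA 13151 genes were called, 5446 higher and 7705 lower, and 5613 passed 2-fold. Against OBP-801, on the same slide, 13143 were called, 5510 higher and 7633 lower, and 5668 passed 2-fold. With median centring 8905 were higher and 4488 lower against TSA, and 8639 and 4609 against OBP-801.

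Androgen-induced genes were higher under NCC-149 than under TSA in 25 of 29 members (median 1.77, adjusted p = 1.7e-08, and adjusted p = 0.00314 with an estimated correlation) and than under OBP-801 in 25 (median 1.90, adjusted p = 1.4e-08, and adjusted p = 0.00302 with it). The same number of ribosome biogenesis genes, 20 of 21, were higher in each (medians 0.85 and 0.92, adjusted p = 0.0136 and 0.0246 with an estimated correlation). Metallothioneins (-3.21 and -3.20, the latter -3.01 with bounds), neuronal markers (-3.27 and -3.10, or -2.11 and -2.09 with bounds), genes known to rise under HDAC inhibitors (-2.60 and -2.57, or -1.62 and -1.55 with bounds) and histone genes (-1.11 and -1.09) were lower with the preset correlation. Replication genes (0.82 and 0.81), mitotic genes (0.53 and 0.69) and luminal markers (0.77 and 0.86) were higher with it. With an estimated correlation none of these 7 lists passed (adjusted p = 0.0759 and 0.0679 for replication genes, luminal markers, neuronal markers and genes known to rise under HDAC inhibitors, 0.118 and 0.108 for mitotic genes, 0.146 and 0.155 for metallothioneins, 0.318 and 0.269 for histone genes). The calls of neuronal markers ended with probes above background on all 12 arrays, where the medians were 0.063 and 0.043. Those of fatty acid synthesis (median 0.73) and acetyltransferase genes (0.54) against TSA ended with quantile normalization, with median centring and with those probes. In all, 14 lists passed against TSA and 13 against OBP-801, 2 of them in each with an estimated correlation. For heat shock genes the medians (-0.29 and -0.20) and the test's direction, up, differed in sign.

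The responses to TSA and OBP-801 were closely alike, and those to NCC-149 were correlated less with either. Across genes, which are not independent replicates, the log2 changes under TSA and OBP-801 had a covariance of 2.78 and a correlation of 0.996. Unchanged groups that shared 3 DMSO arrays, all simulated around the DMSO means, gave a covariance of 0.0075 and a correlation of 0.501. That correlation holds for groups without change, so it is no baseline for the correlations given here. Both compounds raised 7525 genes and lowered 5108, where independent lists would share 4051 and 1874. FADS1, FIBCD1, FSCN2 and POT1, named after their values were seen, rose under TSA and fell under OBP-801. TSA and NCC-149 had a covariance of 0.0732, or 0.0657 beyond the simulated value, and a correlation of 0.184. Both raised 1313 genes and lowered 624, where independent lists would share 1102 and 408. NCC-149 and OBP-801 had a covariance of 0.0686, or 0.0611 beyond the simulated value. Both raised 1277 genes and lowered 620, where independent lists would share 1091 and 412. Of the 51 genes that rose at least 2-fold under NCC-149, 47 did so under TSA and 47 under OBP-801. Random genes matched on level and detection in DMSO, a test chosen after the overlap was seen, gave means of 43.2 (38 to 49 in 1000 draws) and 42.7 (36 to 48). A gene dim on DMSO and NCC-149 arrays was tested only if well above background on all TSA or all OBP-801 arrays. The filter on dim probes can thus bring most of this overlap by itself. Part of each excess may come from the shared DMSO arrays, which were too few to split.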

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

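The tests of slide, detection, array brightness and matched overlap and the counts of unnamed probes and of opposite genes were chosen after the results were seen, and the list medians were planned.

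Probes for long intergenic noncoding RNAs have no symbol and entered no comparison of genes. Of 8259 on the array, 116 were well above background on all TSA arrays and no DMSO array, and 82 the reverse. Under OBP-801 150 were gained and 65 lost, and under NCC-149 11 were gained and 20 lost. Of 4329 tested, 2224 were called under TSA, 1361 up and 863 down, 2130 under OBP-801 and 60 under NCC-149. A probe on chromosome 7 for the interval 155174770 to 155189051 (hg19) rose at least 51.1-fold under TSA and at least 39.9-fold under OBP-801.

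Differences between compounds in the direction of a list's median were looked for, with the direct comparison as the test. Luminal epithelial markers had medians of -0.749 under TSA, -0.816 under OBP-801 and 0.090 under NCC-149, the last -0.011 with spike-in scaling. The direct comparison gave a median of 0.767 for NCC-149 against TSA and 0.862 against OBP-801, which passed with the preset correlation and not with an estimated one (adjusted p = 0.0759 and 0.0679). Fatty acid synthesis genes had a median of 0.248 under NCC-149 and did not pass under TSA or OBP-801 against DMSO (adjusted p = 0.193 and 0.0606). Their direct comparison gave 0.733 against TSA and 0.785 against OBP-801 (adjusted p = 0.0919 and 0.0679 with an estimated correlation). In 991 genes NCC-149 and both other compounds were called in opposite directions against DMSO, with both direct comparisons called as well. Opposite calls were fewer than independent lists would give, 405 and 614 for TSA and NCC-149 against 606 and 743.

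The small changes under NCC-149 were compared across slides, and slide and compound share their arrays. The step from TSA to OBP-801 crosses the same slides, so an effect of the slide alone would give a slope near 1 of that step on the NCC-149 changes, and over the 3301 called genes the slope was -0.1 (SE 0.009). This slope argues against the slide alone as the whole cause. An effect of slide and of row on the slide together could give that step as much variance beyond noise. That holds only if both effects are unrelated over genes, since the steps cross the rows in opposite directions. The ratio was 0.061 (SE 0.005) over the called genes and 0.137 over all genes. The called genes were picked for their NCC-149 change, so the ratio cannot decide this. A weak form of the TSA and OBP-801 response remains open, as do an effect of slide and row together and an effect of 1 slide position alone. Of the genes called for NCC-149, 62.8% moved the same way under OBP-801. Joint calls were more than independent lists would share (1277 against 1091 up and 620 against 412 down). The share of 62.8% does not settle it, since no share was simulated for called genes. Nor does the overlap of rises of at least 2-fold, where 47 of 51 also rose at least 2-fold under TSA against a mean of 43.2 in random genes matched on level and detection in DMSO (38 to 49 in 1000 draws), while 12 of 18 such falls rose under TSA (matched mean 11.7). TSA at lower doses on 1 slide with NCC-149 and DMSO would test for such a weak form.

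Genes below background in DMSO rose in number under TSA and OBP-801. Flags set on each array before scaling showed 1875 probes gained and 340 lost under TSA and 2049 gained and 280 lost under OBP-801, which argues against the 75th-percentile scaling as the cause. For brighter arrays the unscaled 75th percentile was read, and its log2 difference from DMSO was -0.122 for OBP-801 and -0.343 for TSA. The unscaled median signal was higher, at 124 to 134 on TSA and 145 to 153 on OBP-801 arrays against 106 to 109 on DMSO arrays. Negative control spots were dimmer (34.3 and 34.7 against 37.7). A rise of many dim genes could itself lift the median, so these values do not decide whether dim probes were brighter on those arrays. A lower array background was present on NCC-149 arrays too (median 26.5, against 27.3 for TSA and 29.0 for DMSO), and these gained 32 probes and lost 48. A broad onset of silent genes under HDAC inhibition may account for the pattern, as a hypothesis, and 94.7% of the probes gained under TSA were also gained under OBP-801.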

How the results depend on the processing

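The alternatives were chosen before the data were examined. Counts of called genes against DMSO for TSA and OBP-801, and for NCC-149 against either, stayed within 1.5 times under every alternative run. Of genes named for TSA against DMSO, 132 of 138 kept direction and call throughout, of those for OBP-801 133 of 138, for NCC-149 59 of 139 and for TSA against OBP-801 2 of 22. Where no cause is given, the cause was not tested. Probes not above background give only bounds, which limits falls into and rises out of it.

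With an estimated correlation the lists called numbered 2 for TSA, 5 for NCC-149 and 2 for OBP-801 against DMSO, 1 for TSA against OBP-801 and 2 for NCC-149 against each. With fry they numbered 28, 17, 28, 10, 27 and 27, and the heat shock median kept its value with the test's direction turned (0.285 TSA, 0.205 OBP-801, -0.205 NCC-149 against OBP-801, -0.289 against TSA). For NCC-149 against TSA 8 lists passed with probes above background on all 12 arrays, where fewer genes are tested.

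For NCC-149 against DMSO, 840 genes were called with spike-in scaling and 1452 with only the 2 groups, where fewer arrays are fitted. At 2-fold the counts were 1 (normexp), 10 (all 12 arrays) and 39 (only the 2 groups). Leaving out single arrays gave 2025 to 3678 calls, lowest without DMSO replicate 3. For TSA against OBP-801 (224) the counts were 437 (quantile), 0 (spike-in, limma, 2040 at an unadjusted p under 0.05), 897 (normexp), 149 (no filter), 441 (all 12 arrays), 584 (trend and robust) and 18 (only the 2 groups), and 18 to 36 without any 1 array. At 2-fold they were 2 (quantile, median centring, only the 2 groups), 0 (spike-in, normexp), 12 (no filter) and 4 (trend), and 0 to 2 without 1 array. Lists numbered 3 (quantile, median centring, normexp, only the 2 groups) and 2 (spike-in). The covariance of TSA and OBP-801 was 2.5468 (quantile), 1.1881 (normexp) and 2.2716 (no filter), of TSA and NCC-149 0.0578, 0.0517 and 0.0765, and of NCC-149 and OBP-801 0.0536 (quantile) and 0.0463 (normexp). Without 1 DMSO array it was 2.7818 to 2.7885, 0.0767 to 0.0791 and 0.0718 to 0.0747, since fewer shared controls raise it by construction.

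Directions turned for KRT15 under TSA (-0.024 quantile, -0.289 median centring) and OBP-801 (-0.392 median centring), ITGA6 (-0.493 median centring, -0.092 spike-in) and MAGEC2 (-0.002 median centring). With median centring HDAC1 gave -0.544 (TSA) and -0.555 (OBP-801), HDAC6 -0.353 and -0.400, and HDAC8 -0.542 and -0.540. HDAC1 gave -0.143 with spike-in scaling. The mean over probes gave -0.058 and -0.001 for HDAC6 and -0.112 and -0.105 for HDAC8. For NCC-149 against TSA, HDAC1 gave -0.090 (quantile), HDAC6 0.495 and HDAC8 0.576 (median centring), and 0.191 and 0.223 (mean over probes).

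Calls were 59.7% up for TSA, and 33.2% (4472 up, 9008 down) with median centring and 49.1% (5949, 6155) with spike-in scaling. For OBP-801 59.3% became 34.3% (4575, 8777) with median centring. For NCC-149 64.5% became 48.1% (1174, 1269) with median centring, 31.7% (266, 574) with spike-in scaling and 75.7% (3432, 1103) with normexp. For TSA against OBP-801 54.5% became 23.1% (45, 150) with median centring and 76.6% (687, 210) with normexp. With median centring 65.2% (8639, 4609) of calls were higher for NCC-149 against OBP-801 (41.9% before) and 66.5% (8905, 4488) against TSA (41.4% before). The median of all genes moved by -0.144, -0.584 and -0.119 under OBP-801 with quantile, median centring and spike-in scaling, by 0.127 and 0.539 for NCC-149 against OBP-801 with the first 2, and by 0.138, 0.578 and 0.121 against TSA.

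With the replicate number as a block, 3012 genes were called for NCC-149 against DMSO and 105 for TSA against OBP-801, and no other count moved by 1.5 times. Deviations of same-numbered arrays correlated at -0.061 to 0.19, 2 of 18 over 0.1, and in 1 comparison every array matched its own number best, so the numbers are not taken as a pairing. The slide as a block changed no within-slide value and gives none for the 4 comparisons across slides.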

Other observations

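The tests on matched random lists, androgen-repressed genes, neighbouring genes and other splits were chosen after the results were seen, and the values of named genes were planned.

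Values not yet given for named members show further changes shared by TSA and OBP-801. ZEB1, a transcription factor of mesenchymal cells, rose at least 12.9-fold under TSA and at least 13.9-fold under OBP-801, and the endothelial receptor gene KDR at least 9.84-fold under TSA. LAMB3, a laminin gene of basal epithelium, rose by 3.92 and 3.73 on the log2 scale and by 0.74 under NCC-149. SREBF1 rose by 1.75 and 1.59, and SIRT4, a mitochondrial sirtuin, by 3.23 and 3.45. FADS2 fell by 1.21 under TSA, fell by 1.54 under OBP-801 and rose by 0.51 under NCC-149. UGT2B15 fell by 2.84 under TSA, fell by 3.01 under OBP-801 and rose by 0.44 under NCC-149.

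Androgen-induced genes fell further than abundance would give. Their median under TSA and under OBP-801 lay at percentile 0 of 10000 random lists matched on the level in NCC-149 arrays, and the central range of random medians under TSA was -0.437 to 0.280, which argues against a general fall of abundant genes. Loss of androgen signalling alone could raise androgen-repressed genes, whose median under TSA was -0.478 over 6 members, 3 up and 3 down, so the test leaves it open.

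Neuroendocrine and neuronal markers rose somewhat further than most random lists at their level. With genes below background at their bounds, in the list and in the random lists alike, the median was 2.165 under TSA, at percentile 97.8 of matched random lists (central range 0.619 to 2.14), and 2.144 under OBP-801, at percentile 98.7 (0.532 to 2.01). Both lie narrowly outside the range. The list was put to this test after it had risen, so so narrow a margin cannot decide on a general rise of dim genes as the whole cause. Random lists at this level had medians of 1.22 and 1.12, so a general rise may make up part or all of it, and a rise of these genes as a class stays a hypothesis.

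Neighbouring genes could change together. Over 8683 pairs of neighbours within 100 kb, the correlation of log2 changes under TSA after removing the mean of genes at the same level was 0.072, and the highest of 1000 permutations gave 0.030 (p = 1.0e-03, the smallest they can give). Both neighbours rose at least 2-fold in 511 pairs, against a mean of 422 and a highest of 472 in permutations. The correlation was 0.074 under OBP-801 and 0.071 under NCC-149 (highest permutations 0.033 and 0.038), although changes under NCC-149 were far smaller. It passed every permutation and stayed below 0.1 without following the size of the response, so its source stays open.

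Splits of the 6 arrays of each comparison into 3 and 3 number 10, too few for a share under 0.05. The real split and the highest other called by limma 13322 and 0 genes for TSA against DMSO, 1452 and 0 for NCC-149 against DMSO, 13234 and 0 for OBP-801 against DMSO and 18 and 1 for TSA against OBP-801. They called 12839 and 0 for NCC-149 against OBP-801 and 12844 and 0 for NCC-149 against TSA.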
